A study of Mus musculus with 3 samples.

How the data were processed

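Single-cell RNA was measured in 3 libraries of lung and trachea from wild-type C57BL/6 embryos at embryonic day 17.5. Per the labels' protocols, tissue was minced and digested with trypsin-EDTA, collagenase IV and DNase, passed through a 100 um strainer, freed of red cells by lysis, and live cells were sorted by flow cytometry. The protocol text speaks of sorting into lysis plates, whereas the files are matrices of droplet barcodes. The deposited matrices hold raw UMI counts, 1 integer count per gene and barcode, for 27998 genes with Ensembl IDs and symbols, of which 65 symbols are listed more than once. Cell Ranger 1.3.1 and Seurat 3.0.0 are named per the submitters' processing notes, without the role of each, and the genome build behind the counts is not given in the sources used here. Of the gene IDs, 98.74% are in GENCODE M21 (GRCm38) and 94.65% carry the same symbol there, which gave the positions.

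Barcodes shared between libraries were assigned to the library with at least 0.7 of their UMIs. This rule and the UMI minimum were chosen after seeing the data; 12160 of 13514, 2734 of 7491 and 2995 of 7623 barcodes assigned to libraries 1, 2 and 3 fell below the minimum. Cells needed at least 5000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs, which left 1300, 4623 and 4477 cells in libraries 1, 2 and 3, with median mitochondrial shares of 4.35%, 4.55% and 4.62%. Doublets were scored by Scrublet in scanpy 1.11.5, and the highest-scoring cells were removed at an assumed rate of 0.8% per 1000 cells, 14, 171 and 160 cells (345 of 10400, 3.32%). The remaining 10055 cells were clustered (leidenalg 0.10.2) on 2000 variable genes, 30 principal components, 15 neighbours and resolution 1, and again within compartments on 1000 genes and 20 components. List genes, sex-linked, mitochondrial and ribosomal genes, and genes other than markers that correlated above 0.2 with the cell-cycle lists stayed out of the clustering. Clusters were named by 43 marker lists with 298 genes: at least 3 markers detected in 20% of cells and a mean scaled level of at least 0.5 (0.4 in the first round), with clusters above 0.35 for another compartment called mixed, except a mesothelial-like one, since mesothelium carries epithelial markers (108 cells at 0.565, kept in the mesenchymal sums). A cluster whose 10 leading genes held at least 2 markers of another class, and more than of its own, was left unnamed, or called mixed where that class belongs to another compartment. With none of their own and 1 of another class there, 7 clusters kept their names: 51 AT2-like, 209, 109, 95 and 72 general capillary-like, 190 pericyte-like and 171 adventitial fibroblast-like cells. Names end in -like because they rest on these markers alone.

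For each library and class with at least 10 cells, UMIs were summed and compared in edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, library as a block). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes and at least 1 log2 unit. Because the classes come from the same cells that are compared, genes used for clustering and markers were not tested, and an alternative clustered 1 random share of the UMIs and compared the other. The compartments were each set against the other 3 (sums of 2203018 to 36083376 UMIs), and classes in pairs (335507 to 6996929 for AT1-like and AT2-like, 466474 to 7624431 for airway and alveolar, 721403 to 19037016 for contractile and matrix fibroblast-like cells). CPM in the comparisons are scaled by TMM. The pairing of classes by library comes from the shared suspension, and deviations of same-library sums correlated at 0.106 to 0.255. The 26 gene lists with 732 genes were tested by camera (limma 3.58.1, preset correlation 0.01, on log2 CPM with prior count 2), adjusted over the lists of a comparison, with an estimated correlation and fry beside it.

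Named are only list genes: for pairs of classes the 12 largest called changes each way with at least 50 CPM in the higher class and the same direction in 3 libraries; for compartments the 6 largest that exceed every other compartment in 3 libraries; up to 4 genes with the smallest p of each called list; and 18 developmental genes whatever their test said. Groups, comparisons, lists, markers, tests, named genes and most alternatives were fixed before the data were examined. Chosen after seeing the data were the library assignment of barcodes, the UMI minimum, the doublet rate, the rules and limits for unnamed and mixed clusters, and the alternatives UMI minimum 3000, UMI minimum 8000 and all deposited barcodes. Alternatives fixed in advance were DESeq2 1.42.0 size factors or its Wald test, no low-count filter, no replicate block, each library left out, no minimum fold, thinned sums, free RNA subtracted, doublets kept, a stricter cell filter (1000 genes, 5%), resolution 2, 4000 variable genes and count splitting.

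On simulated data with 200 changed genes per comparison, 35.8% to 58.2% of 2-fold, 85.1% to 98.5% of 4-fold and 95.5% to 100% of 8-fold changes were called, and 0 or 1 unchanged genes. A shifted Wnt list was called in all 7 comparisons and 0 of the 25 other lists. The effect of gene correlation here was not tested. Estimating it in the real data ended 67 list calls and kept 25. For pairs of classes few sums are left to estimate spread after the library block, so there this check has little power. Versions were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.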

Results

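The series holds 3 single-cell RNA libraries of lung and trachea from wild-type C57BL/6 mouse embryos at E17.5 (embryonic age in days), late in gestation, when the distal tips of the lung are widening into air sacs. The design text names 3 lungs and tracheas and the labels number 3 replicates, without saying which litter each came from, so the p-values measure the spread between these libraries. All 3 form 1 group, and the comparisons are therefore between cell classes of the same libraries, here numbered 1 to 3 as in the labels. The matrices list 19068, 20113 and 20333 barcodes with 55430817, 93754669 and 88166810 UMIs (counted molecules) in libraries 1, 2 and 3. Because 17627 of the 34940 distinct barcodes are listed in more than 1 library, a barcode was kept only in the library that held at least 0.7 of its UMIs. With at least 5000 UMIs per cell, limits on genes and mitochondrial UMIs, and doublets removed, 1286, 4452 and 4317 cells remained. The minimum was chosen after seeing the data, and a minimum of 3000 leaves 2657, 4628 and 4520, so library 1 depends on it most. Their median depth before doublets were removed was 11738.5, 12266 and 11857 UMIs.

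Which cells make up the lung and trachea shortly before birth was asked first. Mesenchymal cells, the fibroblasts, pericytes and muscle of the organ, were the largest compartment at 56.2% ± 11.2 (SD, n = 3) of the cells. Endothelial cells, which line vessels, made up 14.3% ± 2.12, immune cells 10.6% ± 0.658 and epithelial cells, which line airways and air sacs, 8.60% ± 2.08. Small clusters outside these compartments were erythroid-like (0.156%, 0.337% and 0.649% of libraries 1, 2 and 3), skeletal muscle-like (0.622%, 0.225% and 0.463%) and glia-like (0.0778%, 0.449% and 0.324%). Clusters that carried the marker genes of more than 1 compartment held 9.13% ± 10.6 and were kept out of the comparisons. They took 21.3% of library 1 (exact 95% binomial interval 19.1 to 23.6), 3.62% of library 2 (3.09 to 4.21) and 2.48% of library 3 (2.04 to 2.99). Library 1 also had the lowest mesenchymal share, 43.3% (40.6 to 46.1) against 63.7% (62.3 to 65.2) and 61.7% (60.2 to 63.1). The enzyme digestion, the lysis of red cells, the live-cell sort and the UMI minimum can each set these shares, and the intervals cover counting error only. With all deposited barcodes kept, the shares were 20.2% mesenchymal, 4.92% endothelial, 3.45% immune and 3.20% epithelial.

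**Figure D1:**
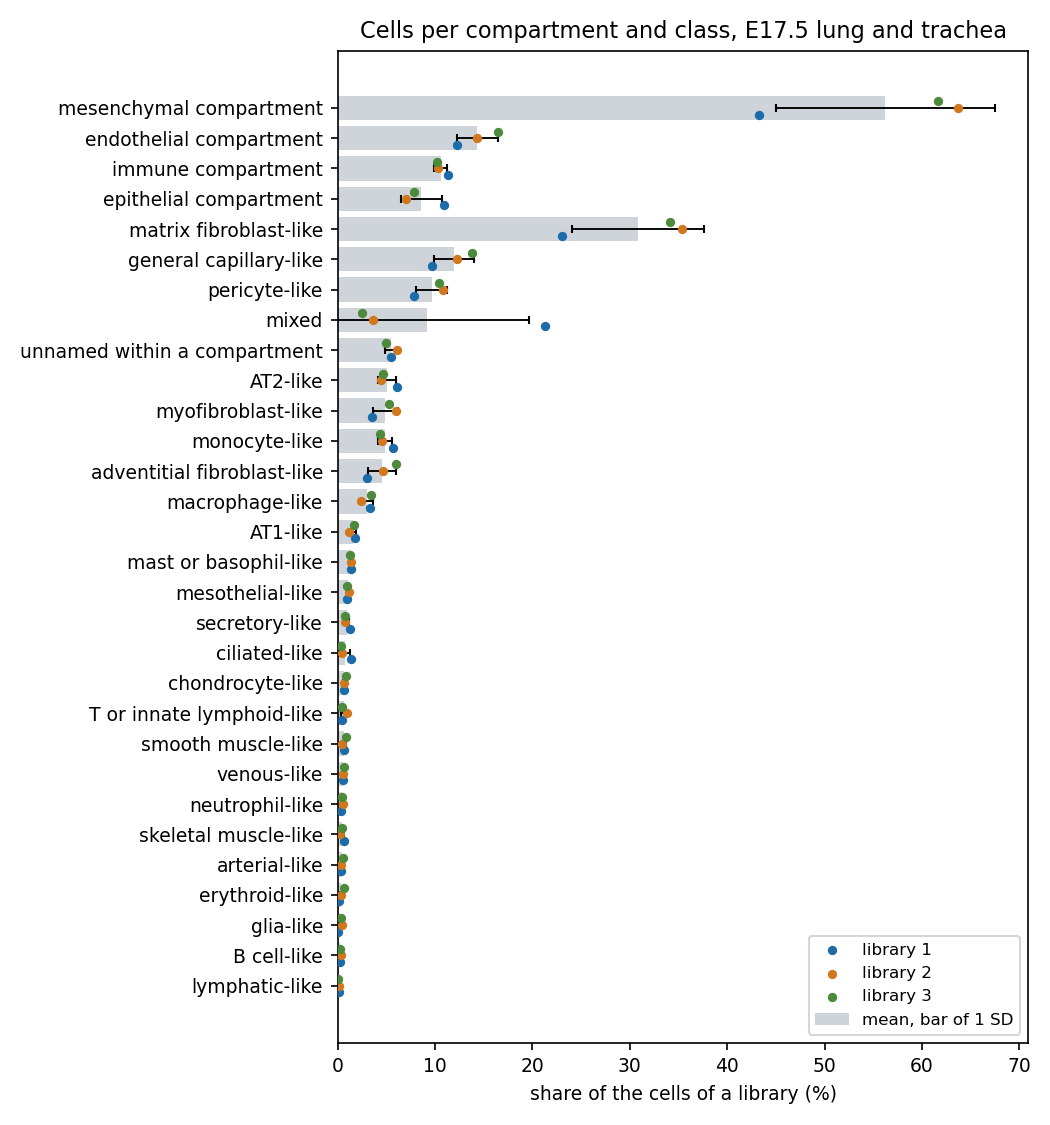
Share of the cells of a library in each compartment (top 4) and class, in percent; grey bars are means of 3 libraries, black bars 1 SD and points the single libraries. The mesenchymal compartment leads with 56.2%, and mixed clusters reach 21.3% in library 1.

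Within the mesenchyme, matrix fibroblast-like cells, the fibroblasts of the air sac walls, made up 30.8% ± 6.80 of all cells. Pericyte-like cells, which wrap capillaries, followed with 9.67% ± 1.59, myofibroblast-like cells with 4.90% ± 1.26 and adventitial fibroblast-like cells of the vessel and airway sheaths with 4.55% ± 1.48. Mesothelial-like cells of the outer lining (1.06% ± 0.116), chondrocyte-like cells of the tracheal rings (0.703% ± 0.154) and smooth muscle-like cells (0.628% ± 0.204) were few. General capillary-like cells were the largest named endothelial class at 11.9% ± 2.05, beside venous-like (0.554% ± 0.0437), arterial-like (0.435% ± 0.128) and lymphatic-like cells (0.120% ± 0.0449). The general capillary-like class includes clusters of 209, 109, 95 and 72 cells with none of its own markers and 1 of another class among their 10 leading genes. In the epithelium, AT2-like cells, which make surfactant, stood at 5.09% ± 0.922, and AT1-like cells, the flat cells of gas exchange, at 1.56% ± 0.326. AT2-like clusters of 115, 114 and 51 cells had no AT2 marker among their 10 leading genes, which limits AT2-like comparisons. Secretory-like airway cells made up 0.917% ± 0.284 and ciliated-like cells 0.732% ± 0.583, the latter resting on library 1 (1.40% against 0.472% and 0.324% in libraries 2 and 3). Immune cells were mainly monocyte-like (4.88% ± 0.698) and macrophage-like (3.04% ± 0.567), with mast or basophil-like (1.33% ± 0.0824), T or innate lymphoid-like (0.647% ± 0.296), neutrophil-like (0.438% ± 0.116) and B cell-like (0.267% ± 0.0809) clusters. Monocyte-like clusters of 178 (led by Naaa, S100a4) and 149 cells (Plet1, Lpl, Ear2, Pparg) had no monocyte marker in their 10 leading genes. A T or innate lymphoid-like cluster of 35 was led by Bcl11b with Ptcra, which thymocytes use. Cells left unnamed inside a compartment were 5.44%, 6.11% and 4.93% of libraries 1, 2 and 3, and no cluster was named aerocyte, basal, neuroendocrine, ionocyte or tuft.

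How many cells were dividing was read from 16 core genes of the G2 and M phases, as the share of cells with at least 2 of their UMIs after each cell was thinned to 2000 UMIs. That share was lowest in the mesenchyme, 21.4% ± 1.31 (SD, n = 3), against 37.7% ± 4.25 in the epithelium, 37.2% ± 2.37 in the endothelium and 36.0% ± 5.33 in immune cells. The mesenchyme was lowest in each of the 3 libraries. Mki67, a gene of dividing cells, was at 180.5 ± 24.9 CPM in the mesenchyme, 195 ± 57.3 in epithelial, 326 ± 71.3 in endothelial and 347 ± 42.2 in immune cells. It was higher in the epithelium than in the mesenchyme in library 1 alone, so no order is read between these 2 compartments. By class, monocyte-like cells reached 45.2% ± 3.58, general capillary-like cells 41.3% ± 2.39, AT2-like cells 40.3% ± 6.02 and pericyte-like cells 32.5% ± 4.34. Lower shares were seen in AT1-like (27.1% ± 1.11), matrix fibroblast-like (18.2% ± 1.35) and adventitial fibroblast-like cells (15.5% ± 4.39). Ciliated-like cells gave 56.1% ± 11.6 but Mki67 at 127 ± 48.2 CPM against 212 ± 77.2 CPM in AT2-like cells, lower in libraries 1 and 2 only, while Top2a, Cdk1 and Cdc20 were higher in all 3, so no order is read between those classes, and none between AT2-like and pericyte-like cells. Neutrophil-like cells gave 12.1% ± 11.2 in the 2 libraries with at least 10 of them (median depth 7512 UMIs), but Camp, Ngp and Ltf led them, genes of immature neutrophils, so they give no clean background level. Shares were also low in myofibroblast-like (11.8% ± 2.66, 11196 UMIs), mesothelial-like (9.96% ± 8.80, 14740 UMIs) and, in 2 libraries each, arterial-like (9.33% ± 3.77, 12212 UMIs), venous-like (5.77% ± 8.16, 9968.5 UMIs) and smooth muscle-like cells (5.41% ± 0.207, 10278 UMIs). How much of such low shares is background was not measured. No cell was shallower than the thinning depth, and without thinning the compartment shares were 82.9% epithelial, 78.6% endothelial, 79.99% immune and 69.5% mesenchymal. No test was run on these shares.

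**Figure D2:**
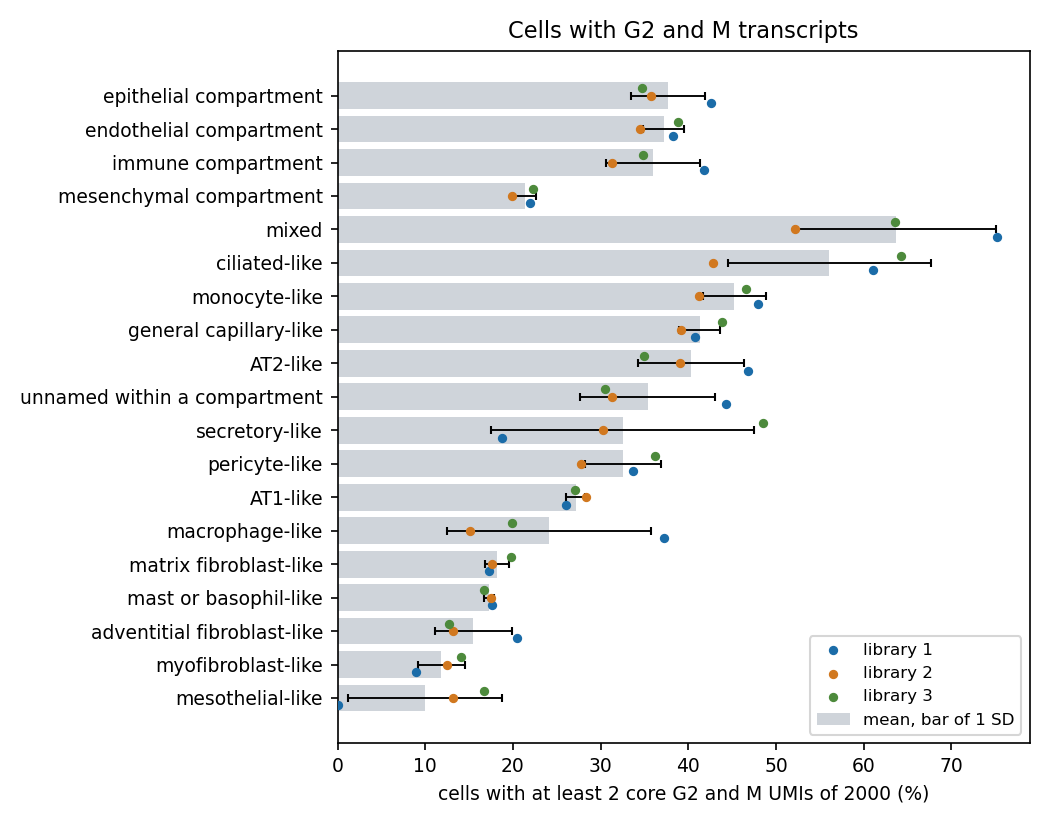
Share of cells with at least 2 UMIs of the core G2 and M genes after thinning to 2000 UMIs, in percent, for compartments (top 4) and for classes with at least 10 cells in each of the 3 libraries; grey bars are means, black bars 1 SD and points single libraries. The mesenchymal compartment is lowest of the 4 at 21.4%.

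What sets lung epithelium apart from the other compartments was asked of its summed counts, each fold change being the log2 difference (± SE) from the mean of the log levels of the other 3 compartments. The 6 list genes with the largest excess were the claudins Cldn6 (5.72 ± 0.092) and Cldn3 (5.63 ± 0.044), which seal tight junctions, and the transcription factors Elf5 (5.68 ± 0.090), Nkx2-1 (5.64 ± 0.057), Irx5 (5.54 ± 0.089) and Foxa2 (5.44 ± 0.098). Nkx2-1, which specifies lung and thyroid, stood at 426 ± 21.7 against 8.79 ± 0.983 CPM (SD, n = 3) as the mean of the other 3. It is a protein-coding gene (ENSMUSG00000001496, chromosome 12, 56531958 to 56536908, minus strand, in GENCODE M21 on GRCm38). Genes of lipid and surfactant synthesis were higher as a group, 17 of 27 measured higher and 1 lower (median log2 fold change 1.35, camera adjusted p = 7.8e-08, adjusted p = 0.021 with an estimated correlation). They included Ctsh (3.86 ± 0.043), a protease that trims surfactant protein, Abca3 (3.41 ± 0.054), the lipid transporter of lamellar bodies, Lpcat1 (3.66 ± 0.045), which makes surfactant phosphatidylcholine, and Sftpd (5.24 ± 0.10), a surfactant collectin. All 6 leading genes and these 4 were higher in 3 of 3 libraries (edgeR quasi-likelihood, adjusted p of at most 3.2e-31).

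Ion and fluid transport genes were also higher, 16 of 25 measured higher and 2 lower (median log2 fold change 3.16, camera adjusted p = 5.9e-05, adjusted p = 0.053 with an estimated correlation). Atp1b1 (4.48 ± 0.065), a subunit of the sodium pump, the potassium channel Kcnk1 (5.00 ± 0.092) and the chloride channel Ano1 (3.66 ± 0.092) were among them. Hippo and mechanical response genes had 9 of 13 measured higher and 0 lower (median log2 fold change 1.31, camera adjusted p = 4.0e-04, adjusted p = 0.053 with an estimated correlation). Cyr61 (1.98 ± 0.042) and Tead1 (1.60 ± 0.063) were among those called. The guidance cues of the semaphorin, ephrin and Slit list had 13 of 30 measured higher and 2 lower (median log2 fold change 0.63, camera adjusted p = 0.0078, adjusted p = 0.32 with an estimated correlation). Sema3e (4.72 ± 0.10) and Epha4 (2.99 ± 0.084) were in this group. Tight and adherens junction genes had 9 of 16 measured higher and 5 lower (median log2 fold change 2.49, camera adjusted p = 0.022, adjusted p = 0.22 with an estimated correlation). The desmosome gene Dsp (5.28 ± 0.085) was among them. FGF pathway genes had 10 of 21 measured higher and 6 lower (median log2 fold change 0.94, camera adjusted p = 0.038, adjusted p = 0.28 with an estimated correlation), with the receptor Fgfr2 (3.60 ± 0.058) and the FGF-responsive factor Etv5 (3.93 ± 0.058), but without library 1 this list gave a camera adjusted p of 0.09998. The Hippo, guidance and FGF lists were also called higher in the mesenchyme and lower in immune cells. As groups they are therefore not particular to the epithelium.

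Lower as groups were chemokines and cytokines, 31 of 40 measured lower and 5 higher (median log2 fold change -2.28, camera adjusted p = 1.2e-05, adjusted p = 0.053 with an estimated correlation). Cxcl12 (-3.23 ± 0.15) and Ccl4 (-2.50 ± 0.11) were among those called. Interferon response genes had 12 of 20 measured lower and 1 higher (median log2 fold change -1.65, camera adjusted p = 1.2e-05, adjusted p = 0.22 with an estimated correlation). The antiviral membrane genes Ifitm3 (-2.42 ± 0.058) and Bst2 (-1.96 ± 0.078) were in this group. Vascular signalling genes had 16 of 26 measured lower and 2 higher (median log2 fold change -1.49, camera adjusted p = 0.0017, adjusted p = 0.053 with an estimated correlation), from Plxnd1 (-3.41 ± 0.085) and Ramp2 (-2.82 ± 0.077) to Vegfa, which was higher (1.87 ± 0.073). Integrins had 11 of 20 measured lower and 4 higher (median log2 fold change -1.60, camera adjusted p = 0.0060, adjusted p = 0.081 with an estimated correlation). Itga4 (-4.03 ± 0.14) and Itga5 (-3.05 ± 0.12) were lower and Itgb6 (5.09 ± 0.14) higher. S phase genes had 2 of 32 measured lower and 0 higher (median log2 fold change -0.43, camera adjusted p = 0.0013, adjusted p = 0.53 with an estimated correlation), and the 2 were the helicase genes Mcm3 (-1.02 ± 0.067) and Mcm4 (-1.06 ± 0.078). Both missed the fold minimum without library 2 (-0.87 and -0.90), Mcm3 also without library 3 (-0.98). In G2 and M phase genes none of 48 was called (median log2 fold change -0.30, camera adjusted p = 0.011, adjusted p = 0.53 with an estimated correlation), and the list gave a camera adjusted p of 0.065 without library 3. The share of dividing cells ran the other way, with the highest mean of the 4 compartments in the epithelium, so the epithelium is not read as dividing less, and the cause of the difference was not tested.

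Of 11390 tested genes, 1543 were called higher and 1101 lower (edgeR quasi-likelihood, adjusted p under 0.05 and at least 1 log2 unit), 200 and 220 of them among the 696 tested list genes. The other 14 lists were not called (camera adjusted p from 0.050 to 0.97), and counts adjusted over the list alone were the same for all 26. Beside 141, 313 and 337 cells compared in libraries 1, 2 and 3, mixed epithelial clusters were kept out. The largest (71, 37 and 38 cells), with AT2 markers, was led by Pcdh17 and the endothelial genes Cdh5 and Cd93. Others held 55, 36, 27, 19 and 11 (9, 19, 27, 12 and 10 in library 1). Kdr (-1.25 ± 0.10) turned to 2.78 with free RNA subtracted, so no direction is read. Of the 58 named genes called here, 48 were called under every alternative tried. Each gene given with a fold change passed (edgeR adjusted p of at most 7.3e-13) and went the same way in 3 of 3 libraries.

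In the endothelium the leading list genes were the SoxF transcription factors Sox18 (6.32 ± 0.091), Sox7 (5.98 ± 0.10) and Sox17 (5.89 ± 0.082), which direct vessel formation. With them stood the receptors Tie1 (5.88 ± 0.064), Kdr (5.72 ± 0.055) and Robo4 (5.65 ± 0.096). Kdr, the main receptor of VEGF-A, was at 492 ± 6.21 against 9.69 ± 0.425 CPM (SD, n = 3) as the mean of the other 3 compartments, and is a protein-coding gene on chromosome 5, 75932827 to 75978458, minus strand (ENSMUSG00000062960). Vascular signalling genes were higher together, 19 of 26 measured higher and 4 lower (median log2 fold change 3.48, camera adjusted p = 1.5e-07, adjusted p = 0.025 with an estimated correlation). Among them were Calcrl (5.25 ± 0.053) and Ramp2 (5.32 ± 0.044), which together form the adrenomedullin receptor. All of these were higher in 3 of 3 libraries (edgeR adjusted p of at most 3.8e-33). Interferon response genes had 9 of 20 measured higher and 2 lower (median log2 fold change 0.87, camera adjusted p = 0.012, adjusted p = 0.40 with an estimated correlation). Bst2 (2.89 ± 0.052) and Ifitm3 (1.47 ± 0.044) were higher and Ifitm1 (-3.18 ± 0.098) lower.

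Lower in endothelium were immediate early and stress response genes, 8 of 19 measured lower and 0 higher (median log2 fold change -0.89, camera adjusted p = 3.7e-07, adjusted p = 0.24 with an estimated correlation). Fos (-2.52 ± 0.058) was at 186 ± 20.5 against 1076 ± 5.30 CPM, and Nr4a1 (-2.52 ± 0.067), Fosb (-2.38 ± 0.068) and Egr1 (-1.41 ± 0.050) were lower too. Chemokines and cytokines had 28 of 40 measured lower and 3 higher (median log2 fold change -2.13, camera adjusted p = 8.5e-06, adjusted p = 0.048 with an estimated correlation), while Cxcl12, which attracts blood-forming and immune cells, was higher (4.33 ± 0.079). Innate defence genes had 11 of 15 measured lower and 0 higher (median log2 fold change -1.94, camera adjusted p = 8.5e-06, adjusted p = 0.025 with an estimated correlation). Anxa1 (-3.58 ± 0.11) and Lgals3 (-3.33 ± 0.11) were among them. Lipid and surfactant genes had 12 of 27 measured lower and 0 higher (median log2 fold change -0.85, camera adjusted p = 8.5e-06, adjusted p = 0.025 with an estimated correlation). Fabp5 (-1.41 ± 0.061) was among those called. Wnt pathway genes had 20 of 41 measured lower and 4 higher (median log2 fold change -1.06, camera adjusted p = 0.012, adjusted p = 0.18 with an estimated correlation). The receptor Fzd2 (-2.43 ± 0.12) was lower and Fzd4 (3.54 ± 0.064), a receptor used in vessel growth, higher. FGF pathway genes had 9 of 21 measured lower and 2 higher (median log2 fold change -0.89, camera adjusted p = 0.0092, adjusted p = 0.18 with an estimated correlation). Etv5 (-2.37 ± 0.11) was lower and the feedback inhibitor Spry4 (1.95 ± 0.11) higher. Glucocorticoid response genes had 4 of 9 measured lower and 1 higher (median log2 fold change -0.68, camera adjusted p = 0.038, adjusted p = 0.18 with an estimated correlation). Klf9 (-2.25 ± 0.11) was lower and Sgk1 (2.74 ± 0.11) higher. Ion and fluid transport genes had 15 of 25 measured lower and 4 higher (median log2 fold change -1.66, camera adjusted p = 0.043, adjusted p = 0.23 with an estimated correlation). Atp1b1 (-3.21 ± 0.12) was lower and the water channel Aqp1 (3.16 ± 0.091) higher.

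Cell-cycle genes were higher as groups without any single member being called. Camera called the list of 32 S phase genes (median log2 fold change 0.50, camera adjusted p = 8.5e-06, adjusted p = 0.44 with an estimated correlation) and that of 48 G2 and M phase genes (median log2 fold change 0.46, camera adjusted p = 2.3e-08, adjusted p = 0.23 with an estimated correlation), and neither call held with the latter. Of 11390 tested genes, 945 were called higher and 1472 lower, 149 and 267 among the 696 tested list genes. The other 14 lists were not called (camera adjusted p from 0.058 to 0.98). Counts adjusted over the list alone were the same except for ion and fluid transport, with 16 lower in place of 15. The list calls for vascular signalling, chemokines and cytokines, innate defence and lipid and surfactant synthesis held with an estimated correlation. Clustering on 4000 variable genes, which changes both the classes and the genes tested, gave 1552 called genes in place of 2417. With free RNA subtracted the balance turned to 1249 higher and 1118 lower. Of the 55 named genes called here, 40 were called under every alternative tried. All genes given with a fold change passed (edgeR adjusted p of at most 3.8e-17), each in the same direction in 3 of 3 libraries.

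The mesenchyme was led by the potassium channel Kcnk3 (4.56 ± 0.091), the transcription factors Tbx5 (4.52 ± 0.072), Foxf2 (4.50 ± 0.086) and Prrx1 (4.41 ± 0.088), and the ligands Fgf10 (4.42 ± 0.092) and Wnt2 (4.38 ± 0.065). Wnt2, which acts in lung development, was at 132 ± 15.4 against 6.56 ± 0.319 CPM (SD, n = 3) as the mean of the other 3 compartments. It is a protein-coding gene on chromosome 6, 17988940 to 18030585, minus strand (ENSMUSG00000010797). Extracellular matrix genes were higher together, 36 of 47 measured higher and 2 lower (median log2 fold change 2.14, camera adjusted p = 7.2e-11, adjusted p = 0.075 with an estimated correlation). The collagen VI chains Col6a1 (4.26 ± 0.045), Col6a2 (4.13 ± 0.042) and Col6a3 (4.18 ± 0.043) were in this group. Wnt pathway genes had 30 of 41 measured higher and 4 lower (median log2 fold change 2.35, camera adjusted p = 1.9e-07, adjusted p = 0.019 with an estimated correlation). Wnt5a (4.25 ± 0.074) and the receptor Fzd1 (3.10 ± 0.065) were among them. These genes were higher in 3 of 3 libraries (edgeR adjusted p of at most 1.2e-30).

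Imprinted growth genes, which are expressed from the copy of 1 parent, were all called higher, 14 of 14 (median log2 fold change 1.87, camera adjusted p = 1.8e-08, adjusted p = 0.022 with an estimated correlation). Meg3 (2.43 ± 0.037), Plagl1 (2.68 ± 0.047) and the growth inhibitor Cdkn1c (1.95 ± 0.041) were among them. BMP and TGF-beta pathway genes had 26 of 35 measured higher and 1 lower (median log2 fold change 1.65, camera adjusted p = 1.7e-07, adjusted p = 0.017 with an estimated correlation). The TGF-beta binding proteins Ltbp2 (3.73 ± 0.066) and Ltbp4 (2.35 ± 0.059) and the BMP ligand Bmp5 (3.23 ± 0.077) were among those called. Hedgehog pathway genes had 10 of 13 measured higher and 1 lower (median log2 fold change 2.66, camera adjusted p = 1.6e-04, adjusted p = 0.022 with an estimated correlation). The receptor Ptch1 (2.66 ± 0.047), the inhibitor Hhip (4.26 ± 0.072) and the co-receptors Boc (3.84 ± 0.082) and Gas1 (3.95 ± 0.079) were in this group. Hippo and mechanical response genes had 8 of 13 measured higher and 1 lower (median log2 fold change 1.25, camera adjusted p = 3.1e-05, adjusted p = 0.019 with an estimated correlation). Cyr61 (2.15 ± 0.040) and Ctgf (2.32 ± 0.082) were among them. FGF pathway genes had 13 of 21 measured higher and 1 lower (median log2 fold change 1.19, camera adjusted p = 3.6e-04, adjusted p = 0.053 with an estimated correlation). Fgf7 (4.35 ± 0.098) and Etv1 (3.59 ± 0.075) were among those called. Retinoic acid pathway genes had 9 of 14 measured higher and 1 lower (median log2 fold change 1.41, camera adjusted p = 0.0012, adjusted p = 0.031 with an estimated correlation). The synthetic enzyme Aldh1a2 (4.24 ± 0.14) was in this group.

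Guidance cues had 19 of 30 measured higher and 6 lower (median log2 fold change 1.57, camera adjusted p = 0.0018, adjusted p = 0.19 with an estimated correlation). Slit2 (3.03 ± 0.058) and its receptor Robo2 (4.22 ± 0.066) were among them. Growth factors and receptors had 15 of 29 measured higher and 3 lower (median log2 fold change 1.18, camera adjusted p = 0.0025, adjusted p = 0.12 with an estimated correlation). The PDGF receptors Pdgfra (4.29 ± 0.062) and Pdgfrb (4.21 ± 0.061) were among those called. Transcription factors had 36 of 83 measured higher and 27 lower (median log2 fold change 0.75, camera adjusted p = 0.0029, adjusted p = 0.10 with an estimated correlation). Tbx2 (4.13 ± 0.053), Tbx4 (4.20 ± 0.061) and Snai2 (3.96 ± 0.052) were in this group. Glucocorticoid response genes had 4 of 9 measured higher and 1 lower (median log2 fold change 0.74, camera adjusted p = 0.014, adjusted p = 0.076 with an estimated correlation). The receptor Nr3c1 (1.02 ± 0.040) and Hsd11b1 (3.66 ± 0.053), the enzyme that regenerates active glucocorticoid, were among them.

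Lower in the mesenchyme were antigen presentation genes, 15 of 16 measured lower and 0 higher (median log2 fold change -2.34, camera adjusted p = 1.7e-08, adjusted p = 0.019 with an estimated correlation), with the MHC class I genes H2-D1 (-4.00 ± 0.061) and H2-K1 (-3.81 ± 0.074), whose sequences resemble those of other class I genes. Innate defence genes had 12 of 15 measured lower and 0 higher (median log2 fold change -2.13, camera adjusted p = 1.0e-05, adjusted p = 0.019 with an estimated correlation), with Lgals3 (-2.81 ± 0.093), Lyz2 (-2.28 ± 0.073) and Wfdc2 (-1.27 ± 0.065). Wfdc2 turned to 4.42 with free RNA subtracted, so no direction is read. Glycolysis and hypoxia genes had 6 of 25 measured lower and 2 higher (median log2 fold change -0.57, camera adjusted p = 3.8e-04, adjusted p = 0.028 with an estimated correlation). Gpi1 (-1.62 ± 0.048), Pkm (-1.40 ± 0.042) and Gapdh (-1.26 ± 0.036) were among those called. Interferon response genes had 9 of 20 measured lower and 2 higher (median log2 fold change -1.32, camera adjusted p = 0.0080, adjusted p = 0.31 with an estimated correlation). Bst2 (-2.77 ± 0.069) was lower and Ifi27 (1.78 ± 0.051) higher. Chemokines and cytokines had 21 of 40 measured lower and 6 higher (median log2 fold change -1.63, camera adjusted p = 0.013, adjusted p = 0.12 with an estimated correlation), although Ccl11, which attracts eosinophils (4.21 ± 0.057), and Tslp (3.27 ± 0.091) were higher. Lipid and surfactant genes had 8 of 27 measured lower and 3 higher (median log2 fold change -0.32, camera adjusted p = 0.013, adjusted p = 0.075 with an estimated correlation). Ctsh (-2.78 ± 0.058) and Abca3 (-2.87 ± 0.075) were in this group. Junction genes had 8 of 16 measured lower and 3 higher (median log2 fold change -1.02, camera adjusted p = 0.040, adjusted p = 0.18 with an estimated correlation). F11r (-3.02 ± 0.067) was lower and Cdh11 (4.34 ± 0.044), a cadherin of fibroblasts, higher. Without library 3 the junction list gave a camera adjusted p of 0.053.

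Cell-cycle genes were lower in the mesenchyme, with 4 of 32 S phase genes called (median log2 fold change -0.61, camera adjusted p = 2.8e-06, adjusted p = 0.31 with an estimated correlation), Mcm5 (-1.04 ± 0.054) among them. Of 48 G2 and M phase genes, only Lbr (-1.34 ± 0.053) was called (median log2 fold change -0.42, camera adjusted p = 1.9e-07, adjusted p = 0.18 with an estimated correlation). Of 11390 tested genes, 1592 were called higher and 1047 lower by edgeR, 263 and 168 of them among the 696 tested list genes. The other 5 lists were not called (camera adjusted p from 0.27 to 0.95). Counts adjusted over the list alone were the same except for the Wnt pathway (5 lower in place of 4) and transcription factors (28 lower in place of 27). Clustering on 4000 variable genes gave 1705 called genes in place of 2639. Of the 90 named genes called here, 78 were called under every alternative tried. Genes given here with a fold change all passed (edgeR adjusted p of at most 8.2e-19) and kept 1 direction in 3 of 3 libraries.

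Immune cells were led by the cytokine receptor gene Il1rl1 (7.16 ± 0.14), the chemokines Ccl4 (7.11 ± 0.051), Cxcl2 (7.01 ± 0.074) and Ccl3 (6.97 ± 0.053), the chemokine receptor Ccr1 (6.87 ± 0.077) and the transcription factor Spi1 (6.99 ± 0.064). Spi1, which encodes PU.1 and drives myeloid development, was at 377 ± 32.9 against 2.82 ± 0.592 CPM (SD, n = 3) as the mean of the other 3 compartments. It is a protein-coding gene on chromosome 2, 91082390 to 91115756, plus strand (ENSMUSG00000002111). Chemokines and cytokines were higher as a group, 31 of 40 measured higher and 6 lower (median log2 fold change 5.45, camera adjusted p = 1.8e-07, adjusted p = 0.021 with an estimated correlation). Antigen presentation genes were called higher in 16 of 16 (median log2 fold change 3.46, camera adjusted p = 9.0e-09, adjusted p = 0.021 with an estimated correlation). The immunoproteasome subunit Psmb8 (3.84 ± 0.051) and the class II loading gene H2-DMa (5.16 ± 0.082) were among them. Interferon response genes had 15 of 20 measured higher and 0 lower (median log2 fold change 1.84, camera adjusted p = 1.4e-05, adjusted p = 0.11 with an estimated correlation). Ifitm1 (4.92 ± 0.058) was among those called. Innate defence genes had 9 of 15 measured higher and 5 lower (median log2 fold change 4.29, camera adjusted p = 0.037, adjusted p = 0.11 with an estimated correlation). Lyz2 (6.19 ± 0.057), Tlr2 (6.24 ± 0.076) and Cd14 (6.14 ± 0.067) were in this group. The genes named here were higher in 3 of 3 libraries (edgeR adjusted p of at most 1.7e-31).

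Glycolysis and hypoxia genes were higher in immune cells, 13 of 25 measured higher and 3 lower (median log2 fold change 1.05, camera adjusted p = 3.4e-04, adjusted p = 0.024 with an estimated correlation). Hexokinase Hk2 (2.77 ± 0.064) and the lactate transporter Slc16a3 (3.35 ± 0.086) were among them. Immediate early and stress response genes had 8 of 19 measured higher and 0 lower (median log2 fold change 0.80, camera adjusted p = 0.0012, adjusted p = 0.41 with an estimated correlation). Ier3 (2.90 ± 0.054) and Dusp1 (2.21 ± 0.053) were among those called. S phase genes had 3 of 32 measured higher and 0 lower (median log2 fold change 0.63, camera adjusted p = 1.0e-04, adjusted p = 0.42 with an estimated correlation), with Mcm5 (1.10 ± 0.059) and Mcm3 (1.01 ± 0.059), the latter missing the fold minimum without library 2 (0.96) or 3 (0.98). G2 and M phase genes had 1 of 48 measured higher and 1 lower (median log2 fold change 0.30, camera adjusted p = 0.0082, adjusted p = 0.47 with an estimated correlation). Lbr (1.21 ± 0.055) was in this group.

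Lower in immune cells were matrix genes, 43 of 47 measured lower and 1 higher (median log2 fold change -2.29, camera adjusted p = 8.1e-13, adjusted p = 0.055 with an estimated correlation). The collagen IV chains Col4a1 (-3.37 ± 0.054) and Col4a2 (-3.40 ± 0.061) and Sparc (-3.59 ± 0.055) were among them. Imprinted growth genes had 13 of 14 measured lower and 0 higher (median log2 fold change -2.63, camera adjusted p = 1.8e-07, adjusted p = 0.024 with an estimated correlation). Grb10 (-3.45 ± 0.073) and Mest (-2.81 ± 0.060) were among those called. Guidance cues had 25 of 30 measured lower and 1 higher (median log2 fold change -2.27, camera adjusted p = 2.0e-07, adjusted p = 0.059 with an estimated correlation). Sema6a (-3.42 ± 0.15) was lower and Sema4a (5.26 ± 0.14) higher. Hippo and mechanical response genes had 11 of 13 measured lower and 0 higher (median log2 fold change -2.82, camera adjusted p = 1.8e-06, adjusted p = 0.021 with an estimated correlation). Wwtr1 (-3.75 ± 0.11), which encodes TAZ, was in this group. Wnt pathway genes had 28 of 41 measured lower and 1 higher (median log2 fold change -1.61, camera adjusted p = 3.6e-06, adjusted p = 0.023 with an estimated correlation). The receptor Ryk (-2.92 ± 0.090) was among them. Vascular signalling genes had 19 of 26 measured lower and 0 higher (median log2 fold change -1.45, camera adjusted p = 3.6e-06, adjusted p = 0.021 with an estimated correlation). Ephb4 (-3.71 ± 0.17) was among those called. FGF pathway genes had 14 of 21 measured lower and 0 higher (median log2 fold change -1.35, camera adjusted p = 1.4e-05, adjusted p = 0.024 with an estimated correlation). Fgfr2 (-2.70 ± 0.11) was in this group. BMP and TGF-beta pathway genes had 24 of 35 measured lower and 4 higher (median log2 fold change -1.56, camera adjusted p = 2.0e-04, adjusted p = 0.021 with an estimated correlation). Tgfb2 (-3.31 ± 0.12) was lower and Tgfb1 (3.13 ± 0.051) higher.

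Junction genes had 13 of 16 measured lower and 0 higher (median log2 fold change -1.98, camera adjusted p = 2.0e-04, adjusted p = 0.037 with an estimated correlation). Tjp1 (-3.46 ± 0.091) was among them. Hedgehog pathway genes had 11 of 13 measured lower and 0 higher (median log2 fold change -1.69, camera adjusted p = 2.5e-04, adjusted p = 0.024 with an estimated correlation). Gli3 (-2.88 ± 0.16) was among those called. Growth factors and receptors had 17 of 29 measured lower and 3 higher (median log2 fold change -1.43, camera adjusted p = 3.4e-04, adjusted p = 0.073 with an estimated correlation). Kitl (-3.39 ± 0.11), the ligand of Kit, was lower and Hgf (4.18 ± 0.17) higher. Transcription factors had 53 of 83 measured lower and 18 higher (median log2 fold change -1.54, camera adjusted p = 4.3e-04, adjusted p = 0.061 with an estimated correlation), with Runx1 (3.86 ± 0.056) and Irf8 (4.41 ± 0.069) among those higher. Ion and fluid transport genes had 17 of 25 measured lower and 3 higher (median log2 fold change -1.55, camera adjusted p = 0.0049, adjusted p = 0.073 with an estimated correlation). Slc12a2 (-2.53 ± 0.082) was in this group. Of 11390 tested genes, 1463 were called higher and 2078 lower by edgeR, 146 and 336 of them among the 696 tested list genes. The other 5 lists were not called (camera adjusted p from 0.062 to 0.84), and counts adjusted over the list alone were the same except for the uncalled Notch pathway (10 lower in place of 9). Of the 94 named genes called here, 80 were called under every alternative tried. Every fold change printed here belongs to a called gene (edgeR adjusted p of at most 3.1e-17) with 1 direction in 3 of 3 libraries.

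The 18 developmental genes fixed for display whatever their test said are given by class as CPM of the summed counts without TMM scaling (mean ± SD, n = 3). Nkx2-1 was at 533 ± 48.9 in AT1-like, 472 ± 14.2 in AT2-like and 267 ± 49.7 in airway-like cells. Sox2, a factor of the conducting airways, was at 83.1 ± 8.39 in airway-like and 0.553 ± 0.573 in AT2-like cells. Sox9 and Id2, distal tip genes, were higher in AT2-like (189.9 ± 70.3 and 679 ± 168) than AT1-like cells (30.1 ± 5.36 and 196 ± 55.9). Shh, a ligand that epithelium sends to mesenchyme, was at 153 ± 44.0 in AT1-like and 71.0 ± 5.53 in AT2-like cells, and its receptor Ptch1 at 347 ± 52.1 in contractile and 228 ± 23.6 in matrix fibroblast-like cells. Fgf10 was at 104 ± 22.5 in matrix fibroblast-like and 5.29 ± 2.21 in contractile cells, and its receptor Fgfr2 at 302 ± 47.9 in AT2-like and 110.1 ± 17.1 in AT1-like cells. Wnt2 reached 233 ± 13.8 in matrix fibroblast-like cells, Wnt7b 42.9 ± 11.4 in AT2-like cells and the Wnt target Axin2 66.7 ± 2.85 in contractile cells. Bmp4 was at 159.9 ± 75.9 in AT2-like and 95.3 ± 12.5 in contractile cells. Among the classes shown, Vegfa was highest in AT1-like cells (418 ± 109, against 146 ± 29.6 in matrix fibroblast-like cells), and its receptor Kdr in general capillary-like cells (533 ± 46.3). Pdgfa was at 185 ± 17.01 in AT1-like and 153 ± 6.50 in AT2-like cells, and its receptor Pdgfra at 710.3 ± 56.2 in contractile and 93.9 ± 6.67 in matrix fibroblast-like cells. Igf2, an imprinted growth factor, was at 535 ± 125 in AT1-like, 401 ± 49.4 in airway-like and 209.6 ± 12.2 in AT2-like cells.

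**Figure D3:**
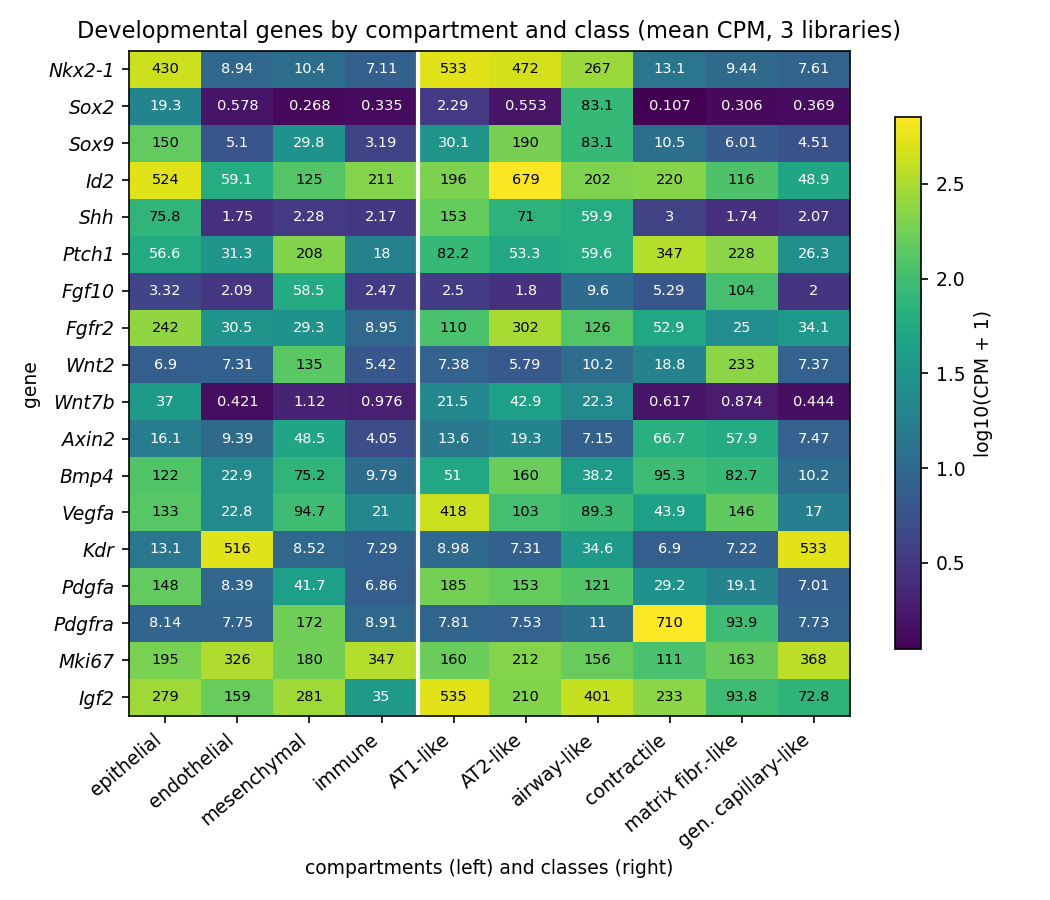
Mean CPM over 3 libraries of 18 developmental genes in the 4 compartments (left of the white line) and 6 classes (right), with colour giving log10(CPM + 1) and the printed value the CPM. Kdr is highest in general capillary-like cells (533), Pdgfra in contractile cells (710.3) and Vegfa in AT1-like cells (418).

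How the alveolar epithelial classes differ was asked by comparing AT1-like with AT2-like cells, with 23, 53 and 74 against 79, 197 and 203 cells in libraries 1, 2 and 3. AT1-like cells had more Vegfa (2.01 ± 0.14), the vessel growth factor, at 421 ± 79.8 against 101 ± 13.2 CPM (SD, n = 3). It lies on chromosome 17, 46016993 to 46032369, minus strand (ENSMUSG00000023951). They also had more of the fluid channels Aqp5 (2.82 ± 0.31), Scnn1a (2.43 ± 0.22) and Aqp1 (1.69 ± 0.23), the guidance cue Sema3a (2.45 ± 0.20), the basement membrane chain Col4a3 (2.10 ± 0.17), the integrin Itgb6 (1.91 ± 0.18), the elastic fibre protein Fbln5 (1.63 ± 0.14) and the imprinted RNA H19 (1.62 ± 0.16). Aqp5 varied between libraries, at 119 ± 98.5 against 15.9 ± 13.3 CPM. Lgals3 (2.10 ± 0.16) and the IGF-binding genes Igfbp6 (2.05 ± 0.18) and Igfbp7 (1.78 ± 0.15) completed the 12 largest increases. AT2-like cells had more Col18a1 (-4.09 ± 0.16) and Col15a1 (-2.23 ± 0.23), basement membrane collagens, the growth regulator Dlk1 (-3.32 ± 0.13), the ephrin receptor Epha7 (-2.86 ± 0.23), and the transcription factors Sox9 (-2.46 ± 0.18), Cebpa (-2.35 ± 0.22) and Etv5 (-1.97 ± 0.15). The surfactant genes Lpcat1 (-1.91 ± 0.15) and Pla2g1b (-2.19 ± 0.22), the class II chaperone Cd74 (-1.996 ± 0.25) and the matrix gene Thbs1 (-1.92 ± 0.19) were likewise lower in AT1-like cells. These 23 genes went the same way in 3 of 3 libraries (edgeR adjusted p of at most 1.5e-05). The lysozyme gene Lyz1 was also called lower, with 2 UMIs in AT1-like and 924 in AT2-like cells, but its sequence is close to that of Lyz2 and its value is uncertain.

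By group, S phase genes were lower in AT1-like cells, 13 of 32 called (median log2 fold change -0.87, camera adjusted p = 5.0e-12, adjusted p = 0.58 with an estimated correlation). Hells (-1.62 ± 0.24), Tyms (-1.28 ± 0.18) and Tipin (-1.06 ± 0.18) were among them. With classes from 4000 variable genes, Tyms (0.10) and Tipin (0.03) turned slightly positive. G2 and M phase genes had 5 of 47 lower (median log2 fold change -0.55, camera adjusted p = 4.5e-09, adjusted p = 0.59 with an estimated correlation), with Cdk1 (-1.25 ± 0.18), but at a UMI minimum of 3000 the list turned to the higher side (camera adjusted p = 0.477). Lipid and surfactant genes had 10 of 24 lower (median log2 fold change -0.54, camera adjusted p = 1.1e-04, adjusted p = 0.58 with an estimated correlation). Fabp5 (-1.88 ± 0.14) and Abca3 (-1.83 ± 0.17) were among those called. FGF pathway genes had 5 of 14 measured lower and 2 higher (median log2 fold change -0.54, camera adjusted p = 0.021, adjusted p = 0.58 with an estimated correlation). Fgfr2 (-1.36 ± 0.13) and Fgf9 (-3.42 ± 0.41) were lower and Fgf18 (2.11 ± 0.27) higher.

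Higher as groups in AT1-like cells were Hippo and mechanical response genes, 3 of 12 called (median log2 fold change 0.40, camera adjusted p = 0.0020, adjusted p = 0.58 with an estimated correlation), namely Wwtr1 (1.07 ± 0.13), Ajuba (1.10 ± 0.18) and Ctgf (1.14 ± 0.19). Junction genes had 2 of 12 higher (median log2 fold change 0.57, camera adjusted p = 0.0031, adjusted p = 0.58 with an estimated correlation), Tjp1 (1.14 ± 0.14) and Pkp2 (1.15 ± 0.20). Matrix genes had 5 of 40 measured higher and 4 lower (median log2 fold change 0.30, camera adjusted p = 0.0023, adjusted p = 0.59 with an estimated correlation). Col4a4 (1.57 ± 0.13) was in this group. Ion and fluid transport genes had 7 of 18 measured higher and 3 lower (median log2 fold change 0.33, camera adjusted p = 0.045, adjusted p = 0.65 with an estimated correlation). Ano1 (1.59 ± 0.14) was among them. Guidance cues had 3 of 20 measured higher and 1 lower (median log2 fold change 0.29, camera adjusted p = 0.039, adjusted p = 0.65 with an estimated correlation). Sema3e (1.29 ± 0.15) was among those called. In the hedgehog list, Shh (1.08 ± 0.14) was the 1 called gene of 5 (median log2 fold change 0.33, camera adjusted p = 0.035, adjusted p = 0.58 with an estimated correlation). Without library 1 the adjusted p of the hedgehog, guidance and ion transport lists became 0.32, 0.35 and 0.19 by camera, and without library 2 that of the hedgehog list became 0.53. Wwtr1 (0.96), Shh (0.97) and Tjp1 (0.92) missed the fold minimum without library 1, and Ctgf (0.83) without library 2.

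Of 7912 tested genes, 145 were called higher and 183 lower by edgeR, 42 and 61 of them among the 453 tested list genes. None of the 10 list calls held with an estimated correlation. The other 16 lists were not called (camera adjusted p from 0.060 to 0.90), and counts adjusted over the list alone were the same except for the uncalled glycolysis (1 higher in place of 0) and antigen presentation lists (2 lower in place of 1). The AT2-like cluster of 114 scored 0.614 on AT1 markers. The number of called genes was 188 by the DESeq2 Wald test, 162 with finer clusters and 102 with classes from 4000 variable genes, in place of 328. The balance of directions is not firm: more genes were higher than lower under 7 alternatives, most with the strict cell filter (172 and 86). Of the 47 named genes called here, 22 were called under every alternative tried. In 3 of 3 libraries each gene given with a fold change went its way (edgeR adjusted p of at most 3.1e-04).

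Airway-like cells (ciliated-like and secretory-like, 34, 54 and 47 cells in libraries 1, 2 and 3) were compared with alveolar-like cells (AT1-like and AT2-like, 102, 250 and 277 cells) to ask what separates the proximal from the distal epithelium. Sox2 (6.41 ± 0.22) led, at 79.6 ± 5.16 against 0.872 ± 0.263 CPM (SD, n = 3). It lies on chromosome 3, 34650405 to 34652461, plus strand (ENSMUSG00000074637) and specifies conducting airway. Next came Aldh1a1 (4.62 ± 0.16), an enzyme that makes retinoic acid, the potassium channel Kcnk2 (2.50 ± 0.14) and the chaperones Hsp90aa1 (2.14 ± 0.060) and Hsph1 (1.67 ± 0.17). The remaining increases were Cdkn1c (1.56 ± 0.11), the sterol enzyme Sqle (1.55 ± 0.15), the tubulin Tubb4b (1.51 ± 0.087), Ckap2l (1.43 ± 0.12), Scnn1a (1.34 ± 0.12), Ifitm3 (1.26 ± 0.095) and the Notch target Hes1 (1.13 ± 0.091). Lower in airway-like cells were the EGF receptor ligand Areg (-2.38 ± 0.14), Igfbp6 (-2.34 ± 0.13), the secreted chaperone Clu (-1.99 ± 0.17), Dlk1 (-1.92 ± 0.080), the collagens Col18a1 (-1.92 ± 0.15) and Col15a1 (-1.85 ± 0.14) and the distal factors Etv5 (-1.89 ± 0.099), Irx1 (-1.74 ± 0.095) and Id2 (-1.68 ± 0.073). Bmp4 (-1.82 ± 0.13), the Wnt inhibitor Nkd1 (-1.78 ± 0.16) and Lpcat1 (-1.69 ± 0.077) were lower too. All 24 went the same way in 3 of 3 libraries (edgeR adjusted p of at most 6.0e-06).

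By group, Notch pathway genes were higher in airway-like cells, 3 of 11 measured higher and 1 lower (median log2 fold change 0.91, camera adjusted p = 0.037, adjusted p = 0.67 with an estimated correlation), with the ligand Jag1 (2.27 ± 0.15) and Hes1, which missed the fold minimum without library 2 (0.98). Retinoic acid pathway genes had 3 of 9 higher (median log2 fold change 0.47, camera adjusted p = 0.037, adjusted p = 0.67 with an estimated correlation). Rbp4 (3.73 ± 0.25) and the receptor Rarb (2.95 ± 0.32) were in this group. FGF pathway genes had 6 of 17 measured lower and 1 higher (median log2 fold change -0.74, camera adjusted p = 0.028, adjusted p = 0.67 with an estimated correlation). Fgfr2 (-1.19 ± 0.093) and Fgf9 (-2.10 ± 0.22) were among them. Lipid and surfactant genes had 7 of 26 measured lower and 2 higher (median log2 fold change -0.35, camera adjusted p = 0.028, adjusted p = 0.67 with an estimated correlation). Ctsh (-1.18 ± 0.054) and Abca3 (-1.24 ± 0.10) were among those called. Hippo and mechanical response genes had 1 of 13 lower, Ctgf (-1.74 ± 0.20) (median log2 fold change -0.43, camera adjusted p = 0.028, adjusted p = 0.67 with an estimated correlation), antigen presentation genes 1 of 12, Cd74 (-1.93 ± 0.18) (median log2 fold change -0.43, camera adjusted p = 0.028, adjusted p = 0.67 with an estimated correlation). None of 32 S phase genes was called (median log2 fold change -0.22, camera adjusted p = 0.028, adjusted p = 0.67 with an estimated correlation). With 2 libraries in place of 3 fewer of these calls remained. Without library 1, 2 or 3, 1, 1 and 4 of the 7 stayed called, and the FGF, Notch and retinoic acid lists were lost in each case (camera adjusted p from 0.054 to 0.091).

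Of 9089 tested genes, 570 were called higher and 223 lower by edgeR, 55 and 65 of them among the 531 tested list genes. None of the 7 list calls held with an estimated correlation. The other 19 lists were not called (camera adjusted p from 0.13 to 0.83), and counts adjusted over the list alone were the same except for Hippo (2 lower in place of 1) and the uncalled matrix list (6 higher in place of 5). Kdr was called higher in airway-like cells (2.11 ± 0.18), at 33.2 ± 1.07 against 7.92 ± 1.55 CPM, an endothelial gene that stands at 533 in general capillary-like cells. With all deposited barcodes kept, 1341 genes were called in place of 793. Of the 36 named genes called here, 33 were called under every alternative tried. Fold changes are given only for called genes (edgeR adjusted p of at most 1.9e-05), all with 1 direction in 3 of 3 libraries.

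The last comparison set contractile mesenchyme, of which 537 of 600 cells were myofibroblast-like and the rest smooth muscle-like (53, 284 and 263 cells in libraries 1, 2 and 3), against matrix fibroblast-like cells (296, 1575 and 1473). Contractile cells were marked by Wnt genes, namely the receptor Lgr6 (7.30 ± 0.13) and the secreted inhibitors Wif1 (6.08 ± 0.13) and Notum (5.495 ± 0.16). Lgr6 stood at 173 ± 35.2 against 0.938 ± 0.165 CPM (SD, n = 3) and lies on chromosome 1, 134983301 to 135105276, minus strand (ENSMUSG00000042793). They also had more Fgf18 (7.24 ± 0.11), Myocd (6.01 ± 0.13), the master co-activator of smooth muscle genes, the guidance genes Sema3c (5.95 ± 0.11) and Plxna2 (3.62 ± 0.066), and Met (5.55 ± 0.18), the receptor of hepatocyte growth factor. Igf1 (4.18 ± 0.040), Gdf10 (4.86 ± 0.13), the integrin Itga9 (4.29 ± 0.068) and Spry1 (3.71 ± 0.086) completed the 12 largest increases. Matrix fibroblast-like cells had more of the homeobox factor Meox2 (-5.01 ± 0.10), Hsd11b1 (-4.94 ± 0.093), Ccl11 (-4.78 ± 0.11), the FGF receptors Fgfr3 (-4.36 ± 0.15) and Fgfr4 (-4.15 ± 0.19) and Fgf10 (-4.19 ± 0.14). The vessel factors Figf, also called Vegfd (-4.14 ± 0.088), and Angpt1 (-3.47 ± 0.13), the matrix genes Npnt (-4.14 ± 0.076) and Col13a1 (-3.72 ± 0.086), Wnt2 (-3.75 ± 0.088) and the BMP binding gene Bmper (-3.56 ± 0.18) were lower in contractile cells as well. All 24 went the same way in 3 of 3 libraries (edgeR adjusted p of at most 3.0e-46).

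By group, BMP and TGF-beta pathway genes were higher in contractile cells, 15 of 32 measured higher and 3 lower (median log2 fold change 0.83, camera adjusted p = 5.9e-06, adjusted p = 0.32 with an estimated correlation). Ltbp2 (3.53 ± 0.064) and Tgfbr3 (2.41 ± 0.065) were in this group. Wnt pathway genes had 15 of 34 measured higher and 7 lower (median log2 fold change 0.60, camera adjusted p = 0.0061, adjusted p = 0.32 with an estimated correlation). Wnt5a (2.03 ± 0.048) was higher. Transcription factors had 19 of 60 measured higher and 8 lower (median log2 fold change 0.49, camera adjusted p = 1.7e-04, adjusted p = 0.32 with an estimated correlation). Foxf1 (2.94 ± 0.056) was higher and Maf (-3.22 ± 0.057) lower. Growth factors and receptors had 9 of 23 measured higher and 4 lower (median log2 fold change 0.54, camera adjusted p = 0.029, adjusted p = 0.33 with an estimated correlation). Pdgfra (2.78 ± 0.047) was higher and Kitl (-2.03 ± 0.086) lower. Immediate early and stress response genes had 5 of 18 higher (median log2 fold change 0.47, camera adjusted p = 7.8e-06, adjusted p = 0.32 with an estimated correlation), with Atf3 (2.77 ± 0.086) and Btg2 (1.03 ± 0.031), the latter missing the fold minimum without library 2 (0.95). Glucocorticoid response genes had 3 of 9 measured higher and 1 lower (median log2 fold change 0.67, camera adjusted p = 0.016, adjusted p = 0.33 with an estimated correlation). Klf9 (2.45 ± 0.068) and Errfi1 (2.00 ± 0.10) were higher. Imprinted growth genes had 4 of 13 measured higher and 2 lower (median log2 fold change 0.63, camera adjusted p = 0.042, adjusted p = 0.33 with an estimated correlation), with Nnat (3.48 ± 0.042) and H19 (2.64 ± 0.037), and camera adjusted p became 0.061 without library 1 and 0.054 without library 3. Cell-cycle genes were lower, with 15 of 32 S phase genes called (median log2 fold change -0.90, camera adjusted p = 7.2e-09, adjusted p = 0.32 with an estimated correlation). Mcm4 (-1.77 ± 0.11) was among them. Of 48 G2 and M phase genes 5 were called lower (median log2 fold change -0.68, camera adjusted p = 3.9e-09, adjusted p = 0.32 with an estimated correlation). Birc5 (-1.15 ± 0.087) was among those called.

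Of 9477 tested genes, 666 were called higher and 617 lower by edgeR, 132 and 94 of them among the 551 tested list genes. None of the 9 list calls held with an estimated correlation. The other 17 lists were not called (camera adjusted p from 0.057 to 0.99), and counts adjusted over the list alone were the same for all 26. With classes from 4000 variable genes, which also changes the genes tested, 718 genes were called in place of 1283. Of the 47 named genes called here, 42 were called under every alternative tried. As a whole, the genes with a fold change passed (edgeR adjusted p of at most 3.1e-27) and went the same way in 3 of 3 libraries.

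**Figure D4:**
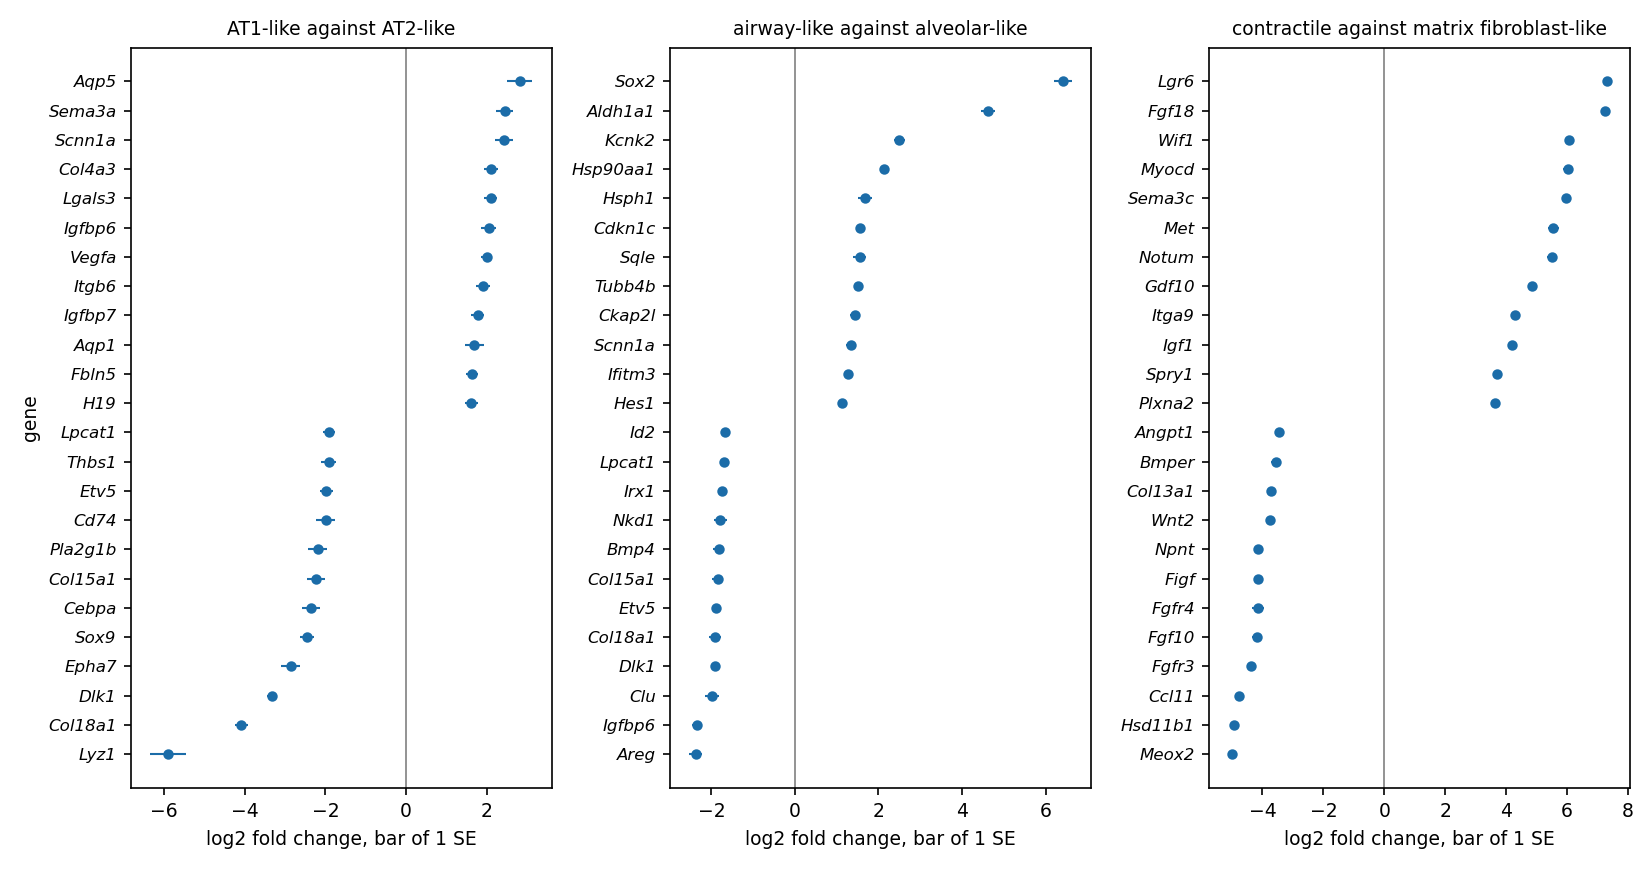
Log2 fold changes (points, bars of 1 SE) of the genes with the largest changes named by rule in each comparison of classes, positive where the first class is higher; fitted on sums of 3 libraries. Lgr6 leads the contractile cells with 7.30 and Sox2 the airway-like cells with 6.41, while the AT1-like value of Lyz1 rests on 2 UMIs.

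A comparison of aerocyte-like with general capillary-like endothelium was planned and could not be made, since no cluster was named aerocyte-like, after the large capillary cells of gas exchange. The nearest, 72 cells with Apln among their leading genes, scored 0.691 on aerocyte and 0.747 on general capillary markers and took the latter name. With the stricter cell filter, 50 cells were named aerocyte-like, and 14 of 8010 tested genes were called against general capillary-like cells by edgeR, 9 higher and 5 lower.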

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

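The tests of shared barcodes and of other groupings of the sums were chosen only after the result was seen. A signal outside the cells compared was that 17627 of 34940 distinct barcodes are listed in more than 1 library, 6947 of them in all 3. Chance reuse of barcodes is excluded, as the UMIs of the copies of a barcode correlate where the main copy has at least 20000 (209 to 727 copies by direction, lowest Spearman correlation of 6 directions 0.913). As the only source, whole molecules of the main library read under another index are excluded too. An estimated 14.6% to 22.7% of the smaller copies, by direction, matches the cell of the main library, with 27.3% for the highest single compartment. For that part such reading is open, and for the rest joining of the other library's molecules to the barcode during amplification. Smaller copies rose in UMIs with the main copy (lowest log-log slope 0.956, same copies), as both would give. No biological explanation was tested, and the cells compared keep only the main copy.

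Cells also carry UMIs of the markers of other compartments. Over all 3 libraries the lowest log-log slope of these UMIs on the total UMIs of the cell, 0.656, could not tell free RNA of the suspension from molecules joined during amplification. The means of libraries 2 and 3 were 1.02 and 0.932, and single compartments ranged from 0.481 (immune cells of library 1) to 1.23 (mesenchyme of library 2), so the source stays open. The subtraction of free RNA took 12.4% to 12.96% of each sum, and no biological explanation was tested.

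The sums of each comparison were also grouped in other ways. Of 50 groupings (the real one and random ones) for each compartment only the real one reached its count of called genes, with 2644 against at most 1195 for epithelium, 2417 against 8 for endothelium, 2639 against 950 for mesenchyme and 3541 against 688 for immune cells. The compartments were made by clustering these cells, so other groupings mix them by construction, and the counts exclude nothing. For the pairs of classes, 10 groupings each, 1 of 10 (the real one) reached 328 for AT1-like against AT2-like, 793 for airway and 1283 for contractile cells, with 0 called in every other, but 10 groupings are too few for a share under 0.05.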

How the results depend on the processing

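No test here was chosen only after the result was seen, except that UMI minima of 3000 and 8000 and all deposited barcodes were added as alternatives after seeing the data; the cause of a change was not tested unless given. Of 427 called named genes, between 384 (free RNA subtracted) and 425 (DESeq2 size factors, no low-count filter) kept their direction and call under each alternative. Reversed were Kdr in epithelium (2.78) and Wfdc2 in mesenchyme (4.42) with free RNA subtracted, Tyms (0.096) and Tipin (0.027) of AT1-like cells with 4000 variable genes, and the G2 and M list of AT1-like cells at UMI minimum 3000 (camera adjusted p = 0.477). Dropping the fold minimum raised the called genes, by construction, to 7542 epithelial, 6996 endothelial, 8368 mesenchymal, 8210 immune, 920 AT1-like, 2551 airway and 5137 contractile. With 4000 variable genes, 1552 endothelial, 1705 mesenchymal, 102 AT1-like and 718 contractile genes were called. The balance turned for AT1-like cells, from 145 higher and 183 lower to more higher than lower, with the Wald test (105 and 83), without replicate 2 (184 and 169), with doublets kept (147 and 140), the strict filter (172 and 86), the count split (213 and 188), UMI minimum 8000 (156 and 127) and all barcodes (254 and 200), and was even without the fold minimum (460 and 460). It turned for endothelium with free RNA subtracted (1249 and 1118, from 945 and 1472), and without the fold minimum for endothelium (3502 and 3494), epithelium (3637 and 3905), immune (4114 and 4096) and contractile cells (2310 and 2827). For AT1-like cells the DESeq2 Wald test called 188 and resolution 2 called 162, and all barcodes called 1341 airway genes. With each replicate left out in turn, counts ranged over 2523 to 2734 epithelial, 2155 to 2451 endothelial, 2567 to 2699 mesenchymal, 3312 to 3593 immune, 330 to 353 AT1-like, 769 to 985 airway and 1306 to 1608 contractile. The fit without the replicate block, which ignores the pairing by library, called 2618, 2375, 2627, 3523, 297, 786 and 1277 in the same order, and it ended the call of 2 named genes and 1 list.

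An estimated correlation left 1 epithelial, 4 endothelial, 9 mesenchymal and 11 immune lists called and 0 for each pair of classes. By fry, 26 epithelial, 19 endothelial, 0 AT1-like and 20 contractile lists were called. AT1-like cells had 5 lists at UMI minimum 3000 and 6 at 8000. Airway cells had 4 at 3000, and 1 to 4 with each replicate left out. Shares became, for epithelium, 10.8% with doublets kept and 3.20% with all barcodes; for endothelium 9.48% with the strict filter, 11.4% at UMI minimum 8000 and 4.92% with all barcodes; for immune cells 11.5% with the strict filter, 9.08% at 3000 and 3.45% with all barcodes; for mesenchyme 20.2% with all barcodes. Dividing shares in epithelium were 27.1% with at least 3 UMIs, 26.3% thinned to 1000, 82.9% not thinned, 42.4% with doublets kept, 43.8% at UMI minimum 3000 and 42.6% at 8000. In endothelium they were 30.4%, 28.1%, 78.6% for the first 3, 39.7% at 3000 and 42.1% at 8000; in mesenchyme 15.6%, 15.6%, 69.5% and 23.1% at 3000; in immune cells 26.6%, 24.5% and 79.99%. The aerocyte comparison has no main value and so no alternatives, apart from the strict filter. Sums thinned to the smaller class, a separate fit that tests other genes, called 243 genes in place of 328 for AT1-like, 705 in place of 793 for airway and 1243 in place of 1283 for contractile cells.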

Other observations

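Several clusters without a class name were led by genes of known tissues; the tests of ciliated-like cells below, and the genes of this part, were chosen only after the result was seen. In the endothelium, 129 unnamed cells were led by genes such as Tmem100, Gja5 and Gja4, the last 2 being connexins of arteries. In the mesenchyme, 317 cells had Smpx, Ibsp and Pth1r. Ibsp and Smpx also led 185 myofibroblast-like cells, and myofibroblast was the nearest class of the 317. A further 82 had Prg4, a joint lubricant, with Tnn and the tendon factor Scx. In the epithelium, 16 cells matched the basal markers but were led by the secretory gene Scgb3a1, the defence gene Reg3g and the basal keratin Krt15, and 11 had Sprr1a, a gene of squamous cells.

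Ciliated-like cells, 18, 21 and 14 in libraries 1, 2 and 3, had raised Ckap2l (114 ± 38.6 against 27.2 ± 5.55 CPM in AT2-like cells), Plk4 (178 ± 68.4 against 22.1 ± 3.17) and Stil (74.0 ± 32.4 against 10.1 ± 3.89), the last 2 acting in centriole assembly. An added share of dividing cells is excluded as the only source, because the median ratio of the other 15 core genes to AT2-like cells was at most 1.31, below the lowest ratio of Ckap2l, 3.38. Cells becoming multiciliated, which make many centrioles, fit: Ccno (212 ± 82.2 against 3.46 ± 1.33), Mcidas (81.8 ± 11.6 against 0.421 ± 0.217) and Myb (318 ± 107 against 3.92 ± 2.44), which act in that step, were at least 39.2 times as high in every library. Mcidas rests on 6 UMIs in AT2-like cells.

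Sex-linked genes differed between libraries. Xist, expressed from the inactive X, had 24, 608 and 80768 UMIs among the 43667021, 76696769 and 70959137 of barcodes assigned to libraries 1, 2 and 3, and genes of the Y chromosome had 7456, 12039 and 613. In library 3, smaller copies of barcodes assigned to libraries 1 and 2 held 1109 and 4058 Xist UMIs among 2165010 and 7343810.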
